A study of Mus musculus with 13 samples.

How the data were processed

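RNA was measured by bulk RNA sequencing in 11 libraries of aortic arch isolates from mice lacking the low-density lipoprotein receptor (Ldlr). Control mice and mice given wild-type bone marrow (BMT, bone marrow transplantation) were each fed standard chow or a cholesterol-rich diet (CRD) for 5 days. The groups held 3 libraries (control on chow), 3 (BMT on chow), 2 (control on CRD) and 3 (BMT on CRD). The labels do not say whether each library came from a separate animal, so the p-values of the gene tests below measure the spread between these libraries. They name no batch, no sex and no time since transplantation. The series also lists 2 single-cell libraries, for which no file was at hand, and these were not analysed here.

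The deposited table holds whole counts per gene for 47729 Ensembl gene identifiers, with 1 column per library and no normalization. The submitters' processing notes name Trim Galore 0.5.0, HISAT2 2.0.5, StringTie 2.0.4, Cell Ranger 3.1, R 4.0.2 and Seurat, and the mm10 genome build, without giving the role of each. The program that made the counts, its annotation and its strand setting are not given in the sources used here. If StringTie made the counts, they are coverage turned back into whole numbers, but nothing in the file says so. Symbols and coordinates came from GENCODE M21 on GRCm38/mm10, which matched 47224 identifiers. The remaining 505 kept their identifier and had no symbol. A count above 0 in at least 1 library was found for 28481 identifiers.

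Library totals ran from 2.38e7 to 3.88e7 counts. A count of 3 in a library corresponded to between 0.0727 and 0.145 CPM (counts scaled to a common library size), which is the least that a library showing 0 could be told from, and such limits cover counting error only. CPM were computed with trimmed-mean-of-M-values (TMM) factors in edgeR 4.0.16, and log2 CPM with a prior count of 2, in R 4.3.3. The filterByExpr rule on the groups kept 20507 genes. Fold changes against a group whose libraries were all at 0 are given as lower bounds, computed against 3 counts over the whole group.

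Genes were tested with the edgeR quasi-likelihood test (robust dispersion, 1 mean per group, all 11 libraries in 1 fit), and p-values were adjusted by Benjamini-Hochberg over the 20507 genes with a threshold of 0.05. The planned comparisons were BMT against control on chow, BMT against control on CRD, CRD against chow in control mice, CRD against chow in BMT mice, and the interaction of transplant and diet. The effects of BMT on chow and on CRD were compared across genes by Pearson and Spearman correlation and the overlap of calls by Fisher's exact test, and the CRD effects likewise. These comparisons, the lists below, the rule for named genes and the first set of alternatives below were fixed before the data were examined.

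The rule for named genes took, in each of the 4 pairwise comparisons, up to 10 genes per direction with the largest fold change among those past the threshold. It required a mean log2 CPM of at least 1 and groups that did not overlap. Predicted gene models, immunoglobulin and T cell receptor segments and sex-linked genes were summarised as classes. For the interaction the overlap condition was dropped. The rule added genes called with the same sign on both diets, members of the lists past the threshold, and Ldlr in every library. Genes named outside the rule are marked as chosen after their values were seen.

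Gene groups were tested with 28 lists of at least 5 measured genes. The functional lists were p53 targets, cell cycle, senescence and secretory, interferon-stimulated, major histocompatibility complex (MHC) class II, cholesterol synthesis, LXR targets, foam cell and lipid-associated macrophage, endothelial adhesion and chemokine, lipoprotein uptake and transcytosis, proteoglycan, matrix and fibrosis, immediate early and stress, and circadian clock genes. The cell type lists were endothelial, smooth muscle, fibroblast, adipocyte, macrophage, monocyte, dendritic, neutrophil, T and NK, B and plasma, mast, erythroid, Schwann and neuron, and cardiac and skeletal muscle markers. Each was tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 28 lists, and again with an estimated correlation and with fry. Camera asks whether the genes of a list shifted relative to all others. At the preset correlation its p does not take up how the genes of a list vary together between these libraries. Fisher's exact test likewise takes genes as its units. The directional p of fry tests whether the genes of a list move, on balance, one way, its mixed p tests whether they change in either direction, and neither compares the list with other genes.

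The alternatives fixed in advance were upper-quartile factors, DESeq2 size factors within edgeR, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, no filter on low counts, a filter of at least 10 counts in at least 6 libraries, only the groups compared, the replicate number as a block, and each library left out in turn. Several choices were added after seeing the data. They were the comparisons averaged over diets and over transplant status, the covariates for sex-linked genes, for thymocyte genes and for the mitochondrial share, the fit without BMT chow libraries 2 and 3, and the exact permutation of list means. The rule for named genes was then applied to the averaged comparisons as well. The thymocyte measure was the mean log2 CPM of 13 measured genes out of 15 listed.

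The pipeline was tested on simulated data built on these group sizes, with known changes of 1, 2 and 4 on the log2 scale. At a change of 1 the edgeR test recovered 4.55% of changed genes for BMT on chow, 1.52% for BMT on CRD, 5.97% for CRD in control, 2.99% for CRD in BMT and 0% for the interaction. At a change of 2 these shares were 59.7%, 31.3%, 52.2%, 50.7% and 19.7%, and at a change of 4 they were 71.2%, 74.2%, 79.7%, 83.3% and 68.2%. The averaged BMT comparison recovered 22.4%, 65.7% and 89.4% at the changes of 1, 2 and 4, and the averaged CRD comparison 22.7%, 73.1% and 89.2%. False calls by edgeR were between 1 of 93 (CRD in control) and 6 of 64 (interaction). Limma voom made 5 false calls of 98 for BMT on chow and 2 of 134 for the averaged BMT comparison. The DESeq2 Wald test made between 65 of 232 and 67 of 155 false calls, so its counts stand only beside counts of 0 and in the closing section. Of 4 lists shifted in the simulation, camera at the preset correlation called 3 or 4 in each comparison and 0 of the other 24. With an estimated correlation between 1 and 4 of them were called. The simulated genes were drawn independently of one another, so the list result does not cover genes that vary together. Over other splits of the real libraries camera called a median of 4 or 5 lists in the comparisons so tested.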

Results

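Polyadenylated RNA was measured in 11 libraries of aortic arch isolates from mice without the low-density lipoprotein receptor. The libraries came from control mice on chow (n = 3), mice given wild-type marrow on chow (BMT, n = 3), control mice on the cholesterol-rich diet for 5 days (CRD, n = 2) and BMT mice on that diet (n = 3). Total counts were 3.75e7, 3.88e7 and 3.25e7 in control chow libraries 1 to 3. They were 2.72e7, 2.70e7 and 3.59e7 in BMT chow libraries 1 to 3. Control CRD libraries 1 and 2 had 2.59e7 and 2.38e7, and BMT CRD libraries 1 to 3 had 3.58e7, 3.58e7 and 2.93e7. Spearman correlations between libraries were 0.917 to 0.957 within groups and 0.905 to 0.950 between groups, over the 20507 genes tested. The biological coefficient of variation was 65.1%.

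The comparison of BMT with control mice on chow asked what irradiation and marrow replacement had left in the arterial wall before any change of diet. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose 2.62-fold, from 92.2 ± 0.356 CPM (SD, n = 3) to 242 ± 36.8 CPM (SD, n = 3). Coro1a, an actin regulator of leukocytes (ENSMUSG00000030707, chromosome 7, 126699773 to 126707787), rose 4.88-fold, from 40.6 ± 10.9 to 198 ± 74.2 CPM. Fyb, an adaptor protein of T cells and other haematopoietic cells (chromosome 15, 6522853 to 6663313), rose 2.34-fold, from 102 ± 12.6 to 237 ± 14.0 CPM. Cxcl13, a chemokine that attracts B cells (chromosome 5, 95956951 to 95961068), fell by 4.08 on the log2 scale, from 32.0 ± 14.4 to 1.88 ± 0.571 CPM. In the edgeR quasi-likelihood test the adjusted p was 0.0274 for Cdkn1a (log2 change 1.39, SE 0.188) and 0.0274 for Coro1a (2.29, SE 0.306). It was 0.0166 for Fyb (1.22, SE 0.153) and 0.0143 for Cxcl13 (-4.08, SE 0.494). For each of the 4 genes 3 of 3 BMT libraries lay beyond 3 of 3 controls, which the rule for named genes required.

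The edgeR test called 9 genes on chow, 8 higher and 1 lower, and 2229 genes had an unadjusted p under 0.05. Limma voom called 171, 94 higher and 77 lower, so both the number and the balance depended on the test. The other 5 called genes were predicted models that overlap repeats: Gm10800 (log2 change 6.24, adjusted p = 0.000152), Gm21738 (4.83, 0.000152), Gm10722 (5.09, 0.000544), Gm26870 (4.91, 0.000544) and Gm10801 (7.69, 0.0136). They lie on chromosomes 2, 9 and 14 and share between 27.5% and 53.5% of their 20-base sequences with called models elsewhere in the genome. The other called genes shared at most 0.076%. Leaving out 1 library gave 4 genes without control chow 2, 4 without BMT chow 2, 5 without BMT chow 3, 16 without BMT chow 1, and 4 without both BMT chow 2 and 3. The calls of Cdkn1a and Coro1a each ended without control chow 1, 2 or 3 or BMT chow 2 or 3. The adjusted p was then 0.0767 to 0.161 for Cdkn1a and 0.0670 to 0.183 for Coro1a. The call of Cxcl13 ended without control chow 2 or BMT chow 1, 2 or 3 (0.0556 to 0.141) and that of Fyb without control chow 2 or 3 or BMT chow 2 or 3 (0.0517 to 0.0944). That of Gm10801 ended without control chow 2 or BMT chow 2 or 3 (0.0504 to 0.0815). Gm10801 had 0 counts in control chow 1 and 2 and 0.255 CPM in control chow 3, and its log2 change ran from 7.09 to 12.1 with each library left out.

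Coro1a was at 113 CPM in BMT chow 1 and at 252 and 229 CPM in BMT chow 2 and 3, the libraries in which thymocyte genes were highest. With the thymocyte mean as a covariate the chow log2 change by edgeR was 1.95 for Coro1a (adjusted p = 0.402), 1.29 for Cdkn1a (0.402) and 1.25 for Fyb (0.267), and these 3 calls ended. Without both BMT chow 2 and 3 that of Coro1a was 1.49 (0.573). The calls of Cxcl13 and the 5 repeat models were kept with the thymocyte covariate. With only the groups compared, the chow calls of Coro1a, Fyb, Cdkn1a and Gm10801 ended (adjusted p up to 0.127).

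Among gene groups on chow, the 26 cell cycle genes were all higher in BMT libraries, with a mean log2 change of 1.89 (camera adjusted p = 2.80e-13, and adjusted p = 0.253 with an estimated correlation). None of the 26 passed over all genes, and 16 rose adjusted over the list alone, among them Top2a, Cdk1 and the proliferation marker Mki67 (18.0 ± 5.39 to 62.2 ± 16.2 CPM). All 16 T and NK cell markers were higher, by a mean of 2.23 (camera adjusted p = 1.39e-07, and adjusted p = 0.253 with an estimated correlation). Cd4, a T helper cell marker that is also among the 13 thymocyte genes, was the 1 of them that rose adjusted over the list alone. Its rise came from BMT chow 2 and 3, at 38.2 and 68.1 CPM. In BMT chow 1 Cd4 was at 5.84 CPM, within the range of the control chow libraries (highest 6.41 CPM, control chow 2). Both lists moved with genes of developing thymocytes, whose mean log2 CPM was 4.02, 5.75 and 6.36 in BMT chow 1 to 3 and 1.90, 4.24 and -0.54 in control chow 1 to 3. With the thymocyte mean as a covariate the cell cycle mean was 0.47 (camera adjusted p = 0.0613) and the T and NK mean 0.71 (camera adjusted p = 0.198). The covariate holds 3 members of the T and NK list (Cd4, Cd8b1 and Lck). Part of the fall of that mean was therefore built in, here and in the other comparisons, and it cannot tell thymus tissue from other T cells. Over the 14 alternatives of each list the adjusted p ran from 4.30e-14 to 0.253 for the cell cycle and from 3.06e-11 to 0.253 for the T and NK markers. Genes of antigen presentation by MHC class II were higher by a mean of 0.68 (8 of 10 positive, camera adjusted p = 0.000182, and adjusted p = 0.253 with an estimated correlation). Of these 0 passed over all genes and 6 rose adjusted over the list alone (H2-Eb1, Ciita, Cd74, H2-DMb1, H2-Aa and H2-DMa). Without both BMT chow 2 and 3 the MHC class II mean on chow was -0.13, although camera still called the list as higher (adjusted p = 0.00131).

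The contractile genes of smooth muscle were lower on chow in all 14 markers, by a mean of -0.69 (camera adjusted p = 8.39e-07, and adjusted p = 0.253 with an estimated correlation). Within the list 7 fell when adjusted over it alone, including Acta2 (9135 ± 1958 to 4409 ± 727 CPM), Myh11 (2393 ± 394 to 1188 ± 169 CPM) and Tagln (816 ± 161 to 509.5 ± 30.3 CPM). None of the 14 passed over all genes. Matrix and fibrosis genes were lower in 21 of 23 (mean -0.49, camera adjusted p = 4.67e-05, and adjusted p = 0.253 with an estimated correlation). Postn, a matricellular protein, was the 1 member that fell adjusted over the list alone. Mast cell markers were lower in 10 of 11 (mean -1.90, camera adjusted p = 0.000478, and adjusted p = 0.253 with an estimated correlation). Of the 11, 5 fell adjusted over the list alone, including Cma1 (180 ± 25.8 to 43.4 ± 8.49 CPM) and Cpa3 (173 ± 45.7 to 26.6 ± 12.9 CPM). Gata2, a transcription factor also of other lineages, rose by the same measure. The p53 targets were higher in 18 of 24 (mean 0.53, camera adjusted p = 0.00244, and adjusted p = 0.253 with an estimated correlation). Cdkn1a passed over all genes, and Aen and Cdkn1a rose adjusted over the list alone. Interferon-stimulated genes were higher in 22 of 27 (mean 0.62, camera adjusted p = 7.88e-06, and adjusted p = 0.323 with an estimated correlation). Irf7 and Zbp1 rose adjusted over the list alone, and the mean was 1.00 without control chow 1.

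The other called lists on chow were endothelial adhesion and chemokine genes (mean 0.56, camera adjusted p = 0.00169, and adjusted p = 0.253 with an estimated correlation) and endothelial markers (0.53, 0.00101, and 0.369 with an estimated correlation). In the same order of values, adipocyte markers had -0.84, 0.00297 and 0.506, erythroid markers 1.70, 0.00933 and 0.506, and cardiac and skeletal muscle markers -0.51, 0.0418 and 0.555. Adjusted over the list alone, Mmrn2 and Egfl7 rose among the endothelial markers, Retn fell among the adipocyte markers, and 0 passed in the other 3. Without BMT chow 1 neither endothelial list was called (camera adjusted p = 0.0840 for both). The erythroid call ended without control chow 2 (0.128) or BMT chow 3 (0.121, mean 0.96), and its mean was -0.64 without both BMT chow 2 and 3. The cardiac call ended without control chow 1 (mean -0.21, 0.184) or BMT chow 1 (-0.14, 0.620), and without BMT chow 2 that mean was -1.01. In all 13 of the 28 lists were called by camera on chow, 0 with an estimated correlation and 1, MHC class II, by fry (adjusted p = 0.0444).

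**Figure D1:**
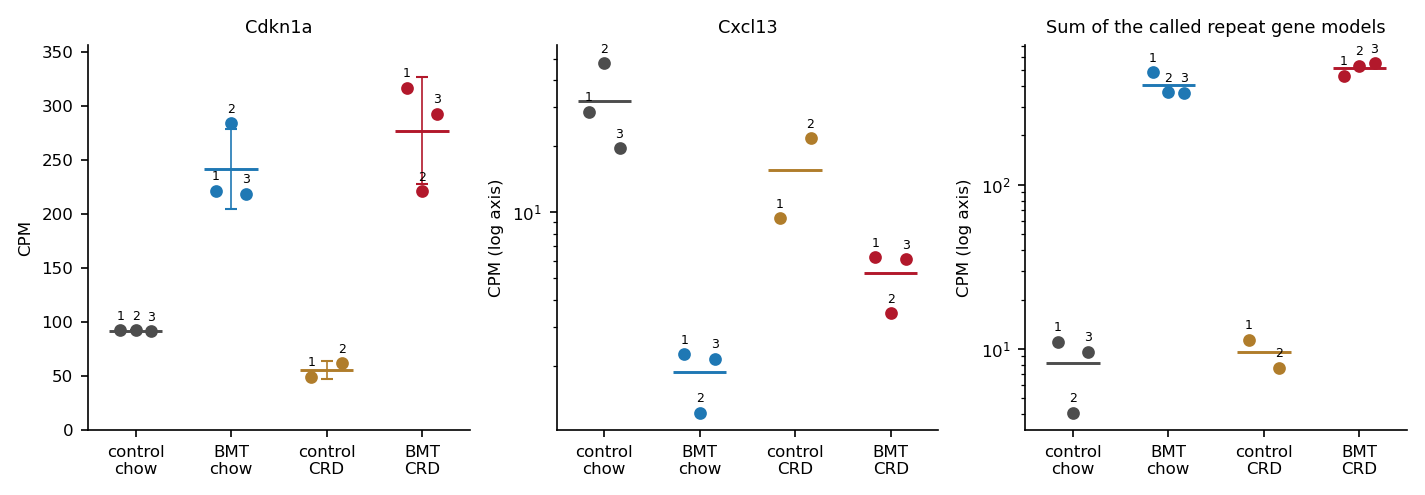
CPM of Cdkn1a, CPM of Cxcl13 on a log axis and the summed CPM of the 5 called repeat models on a log axis, by group (control chow, BMT chow, control CRD, BMT CRD); points are libraries numbered by replicate, horizontal lines are group means, and error bars on the Cdkn1a panel are SD. The repeat sum was 4.10 to 11.4 CPM in the 5 control libraries and 364 to 553 CPM in the 6 BMT libraries.

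The comparison of BMT with control mice on CRD asked whether the artery of marrow recipients differed during the first 5 days of high cholesterol. Cdkn1a rose 4.97-fold, from 55.7 ± 8.68 CPM (SD, n = 2) to 277 ± 49.7 CPM (SD, n = 3). Cyp4f18, a fatty acid hydroxylase of neutrophils and other myeloid cells (chromosome 8, 71988482 to 72009626), rose 4.56-fold, from 26.6 ± 6.97 to 121 ± 15.7 CPM. Napsa, an aspartic protease (chromosome 7, 44572380 to 44586862), rose 13.8-fold, from 0.748 ± 0.445 to 10.3 ± 2.07 CPM. Pkp3, a desmosomal plakophilin (chromosome 7, 141078218 to 141090510), had 0 counts in both control CRD libraries and 6.61 ± 3.62 CPM in BMT CRD, at least 91.4-fold higher. On chow Pkp3 was at 3.5 ± 1.9 CPM in control and 8.6 ± 3.9 CPM in BMT libraries, so that fold rests on the 0 counts in control CRD. The gene models Gm38394, Gm17907, Gm5532 and Gm6361, chosen after their values were seen, likewise had 0 counts in both control CRD libraries and counts in the other 9. By the edgeR quasi-likelihood test the adjusted p was 0.00198 for Cdkn1a (log2 change 2.31, SE 0.227) and 0.0159 for Cyp4f18 (2.19, SE 0.272). It was 0.0429 for Napsa (3.78, SE 0.536) and 0.0275 for Pkp3. For each of the 4, 3 of 3 BMT libraries lay above 2 of 2 controls, again a condition of the rule for named genes.

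The edgeR test called 9 genes on CRD, all higher, and 2697 genes had an unadjusted p under 0.05. The other 5 were Gm10800 (log2 change 5.98), Gm21738 (5.27), Gm10722 (5.93) and Gm26870 (6.43), with adjusted p between 0.000877 and 0.00132, and Gm42688 (chromosome 6, 83101617 to 83109939). Gm42688 was at least 68.7-fold higher, with adjusted p = 0.00198. Gm42688 overlaps Ccdc142 on the same strand, so its counts depend on how reads were assigned between them. Without control CRD 1 the count was 25. The call of Cyp4f18 ended without control CRD 2 or BMT CRD 1 or 3 (0.0568 to 0.102) and that of Napsa without control CRD 2 or BMT CRD 1, 2 or 3 (0.0872 to 0.121). The log2 change of Napsa was 3.28 without control CRD 2 and 4.59 without control CRD 1. The call of Pkp3 ended without control CRD 1 or 2 or BMT CRD 1 or 3 (0.0568 to 0.102). Cdkn1a and the other 5 were called without each of the 5 libraries in turn. With only the groups compared the calls of Cdkn1a (log2 change 2.32), Gm42688 (edgeR adjusted p = 0.247), Cyp4f18, Napsa and Pkp3 ended. With the mitochondrial share as a covariate the call of Cdkn1a ended (log2 change 1.85, 0.171). Those of Cyp4f18 (2.35, 0.248), Napsa (4.31, 0.234) and Pkp3 (0.158) ended too, although the changes of Cyp4f18 and Napsa were no smaller. By limma voom the CRD calls of Gm42688 (0.203), Gm10722 (0.169), Gm26870 (0.0990), Napsa and Pkp3 (both 0.292) ended, which left 4 of the 9.

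All 27 interferon-stimulated genes were higher in BMT libraries on CRD, by a mean of 1.29 (camera adjusted p = 1.40e-10, and adjusted p = 0.319 with an estimated correlation). Of the 27, 18 rose adjusted over the list alone, and 0 passed over all genes. MHC class II genes were higher in 9 of 10, by a mean of 2.00 and a median of 1.23 (camera adjusted p = 4.70e-06, and adjusted p = 0.207 with an estimated correlation). Over all genes 0 passed, and 8 rose adjusted over the list alone, including Cd74 (7520 ± 1865 to 18170 ± 2242 CPM) and H2-DMb1 (59.7 ± 9.29 to 199.9 ± 28.8 CPM). The p53 targets were higher in 17 of 24, by a mean of 0.73 (camera adjusted p = 0.0108, and adjusted p = 0.292 with an estimated correlation). Cdkn1a passed over all genes, and Eda2r, Aen, Sesn2 and Cdkn1a rose adjusted over the list alone. By fry these 3 lists were called, with adjusted p of 0.0214, 0.00294 and 0.00859. The p53 call by camera ended without control CRD 1 (0.177) or BMT CRD 1 (0.0927), and without control CRD 2 the mean was 1.37. With the mitochondrial share as a covariate the p53 mean on CRD was 0.39 and the list was not called (camera adjusted p = 0.594), whereas the interferon and MHC class II lists were.

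Smooth muscle markers were lower on CRD in 10 of 14 (mean -0.32, camera adjusted p = 0.0108, and adjusted p = 0.787 with an estimated correlation). Acta2, Myh11, Synpo2, Itga8 and Tagln fell adjusted over the list alone. Endothelial adhesion and chemokine genes were higher in 13 of 16 (mean 0.70, camera adjusted p = 0.0178, and adjusted p = 0.787 with an estimated correlation). Cx3cl1, Tnfaip3, Selp, Irf1 and Icam1 rose adjusted over the list alone. Endothelial markers (mean 0.45), adipocyte markers (-0.78) and cardiac and skeletal muscle markers (1.42) each had a camera adjusted p = 0.0158, and adjusted p = 0.787 with an estimated correlation. Adjusted over the list alone, Mmrn2 and Egfl7 rose among the endothelial markers and 0 of the adipocyte markers passed. Actc1, Nppa, Myl4, Myl7 and Tnnt2, genes of heart muscle, rose among the cardiac markers adjusted over the list alone. The mitochondrial share of counts was 25.5% and 17.2% in the control CRD libraries against 4.98%, 15.7% and 9.27% in BMT CRD 1 to 3. With that share as a covariate the endothelial, adipocyte and cardiac means were -0.14, 0.47 and -0.00341. Of the 8 lists called by camera, 3 were called without control CRD 1 and 2 without BMT CRD 1. Without BMT CRD 1 the smooth muscle mean was -0.14 (camera adjusted p = 0.247), the adipocyte mean -0.39 and the cardiac mean 0.95. The smooth muscle mean was -0.17 (0.145) without control CRD 2, and the endothelial markers mean was 0.24 without control CRD 1 and 0.86 without control CRD 2. The adhesion call ended without control CRD 1 (0.138), control CRD 2 (0.0683) or BMT CRD 1 (0.188). The adipocyte mean was -0.04 without control CRD 1, -1.20 without control CRD 2 and -1.31 without BMT CRD 2. The cardiac mean was 1.14 (0.488) without control CRD 1 and 2.24 without control CRD 2.

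The BMT effects on chow and CRD were set side by side to ask whether the transplant acted alike under both diets. Cdkn1a, Gm10800, Gm21738, Gm10722 and Gm26870 were called higher on both diets, 5 genes where 0.00395 were expected by chance (Fisher's exact test, two-sided, p = 5.25e-16). The 4 repeat models share sequence, so the 5 are not independent, and by limma voom the CRD calls of Gm10722 and Gm26870 ended. Coro1a had a log2 change of 0.86 on CRD (adjusted p = 0.317), Fyb 0.60 (0.216) and Cxcl13 -1.56 (0.242). On chow Napsa had 1.09 (0.351), Cyp4f18 0.91 (0.175) and Pkp3 1.29 (0.446). In the edgeR test of the interaction the adjusted p was 0.720 for Cdkn1a, Coro1a, Fyb, Cxcl13, Napsa and Cyp4f18 and 0.411 for Pkp3, so none of these was shown to differ between diets. Across all 20507 genes the effects correlated with Pearson's r = 0.102 and Spearman's rho = 0.209, and 59.2% had the same sign. Across the 9910 genes with a mean log2 CPM of at least 3 these were 0.407, 0.445 and 65.9%; genes are not independent replicates. Over all genes Pearson's r was 0.0198 without BMT chow 3 and 0.0440 without control CRD 1.

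The BMT effect averaged over diets, a comparison added after seeing the data, used all 5 control and 6 BMT libraries. Cdkn1a rose 3.61-fold, Aen, an exonuclease induced by p53, rose 2.56-fold, and Eda2r, another p53-induced gene, rose 4.78-fold. Irf7, a regulator of the interferon response, rose 6.55-fold, Zbp1, a sensor of nucleic acids, 2.79-fold, and Stat1 1.75-fold. The MHC class II genes H2-DMb1 (2.51-fold), H2-Ab1 (2.92-fold), H2-Aa (2.02-fold), H2-DMa (1.97-fold) and Cd74 (2.07-fold) rose, as did the endothelial genes Egfl7 (2.15-fold), Mmrn2 (1.92-fold) and Plvap (5.16-fold). Plvap was at 0.580 and 0.481 CPM in control CRD 1 and 2, against 1.39, 6.48 and 4.34 CPM in control chow 1 to 3. The smooth muscle genes Myh11, Acta2, Itga8 and Synpo2 fell by 0.93, 0.96, 1.03 and 1.11 on the log2 scale, and Lpl, Cd36, Fabp4 and Vldlr fell by 0.79, 0.80, 1.43 and 0.89. Of these, Lpl, Cd36 and Fabp4 belong to the foam cell list and Vldlr to the lipoprotein uptake list. Neither list was called for the averaged BMT effect, whereas adipocyte markers were called as lower. Fabp4 was at 1520 CPM in control CRD 1 and 171.5 CPM in BMT CRD 1, where the adipocyte mean log2 CPM was highest (6.49) and lowest (3.85). Whether these falls arose in macrophages or in fat was not tested. Cxcl13 fell by 2.82, from 32.0 ± 14.4 to 1.88 ± 0.571 CPM on chow and from 15.6 ± 8.74 to 5.27 ± 1.56 CPM on CRD. Single libraries ended many of these calls. Of the 43 genes the rule named, 17, 15 and 10 were called without control chow 1, 2 and 3, and 35, 6 and 9 without BMT chow 1, 2 and 3. Without control CRD 1 and 2 these numbers were 8 and 9, and without BMT CRD 1, 2 and 3 they were 26, 21 and 10.

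By the edgeR quasi-likelihood test 243 genes were called in the averaged comparison, 137 higher and 106 lower. Of these 239 had the same sign on both diets and 24 were predicted models. Limma voom called 272, 111 higher and 161 lower, so the balance of directions depended on the test. An unadjusted p under 0.05 was reached by 3684 genes. The adjusted p was 0.000229 for Cdkn1a (log2 change 1.85, SE 0.147), 0.00642 for Irf7 (2.71, SE 0.315), and 0.00734 for Cxcl13 (-2.82, SE 0.339). It was 0.00753 for Usf1 (2.60, SE 0.323), 0.0117 for H2-DMb1 (1.33, SE 0.178), 0.0121 for Napsa (2.44, SE 0.330) and 0.0124 for Synpo2 (-1.11, SE 0.153). All 6 BMT libraries lay beyond all 5 controls for each of these 7, as the rule required of Irf7, Cxcl13, Usf1 and Napsa. The other 36 of the 43 named genes had adjusted p between 0.0181 and 0.0482, and Eda2r, H2-Ab1, Plvap, C1qa, Lpl and Cd36 had BMT and control libraries that overlapped when the diets were pooled. Higher genes among them not yet named were C1qa, Lsp1, Pcdhgb1, Cenpm, Plxdc1, Ets1, Il27ra, Tap2 and Pik3ap1, and lower ones Mcpt4, Agbl3, Cldn10, Zfp2, Tmem117, Cmbl, Zdhhc2, Fgf1 and Zfp931. Leaving out 1 library gave 58, 74 and 36 called genes without control chow 1, 2 and 3, and 378, 21 and 31 without BMT chow 1, 2 and 3. It gave 52 and 73 without control CRD 1 and 2, and 134, 98 and 38 without BMT CRD 1, 2 and 3. Cdkn1a, Cxcl13, Irf7, Napsa and Usf1 were called without each of the 11 libraries in turn. The calls of Irf7, Napsa and Usf1 ended with the thymocyte mean as a covariate, with the mitochondrial share as a covariate and without both BMT chow 2 and 3 (adjusted p up to 0.127). Their log2 changes in these 3 settings were at least 2.24, 2.53 and 2.13, against 2.71, 2.44 and 2.60. The call of Cxcl13 ended without both BMT chow 2 and 3 (0.185), and Cdkn1a was called in all 22 alternatives. The call of H2-DMb1 ended without control CRD 2 (adjusted p = 0.0503) and that of Synpo2 without control chow 3 or BMT chow 2 (up to 0.0643). Both calls also ended with the mitochondrial share as a covariate and without both BMT chow 2 and 3, and that of Synpo2 with the thymocyte mean as a covariate (adjusted p up to 0.204). In these settings the log2 change was at least 1.27 for H2-DMb1 and between -1.15 and -0.98 for Synpo2. The calls of Lpl and Tmem117 ended without any 1 of the 11 (up to 0.144). With the mitochondrial share as a covariate the count was 8, with the thymocyte mean 15, with a term for sex-linked genes 41, and without BMT chow 2 and 3 it was 9. None of the 43 turned its sign in any of the 22 alternatives.

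In the averaged comparison camera called 11 of the 28 lists, 7 higher and 4 lower, and 0 with an estimated correlation (smallest adjusted p = 0.154), while fry called 5. Interferon-stimulated genes were higher in 27 of 27 (mean 0.96, camera adjusted p = 4.69e-11, and adjusted p = 0.293 with an estimated correlation). Irf7, Zbp1 and Stat1 rose over all genes and 15 members rose adjusted over the list alone. MHC class II genes were higher in 9 of 10 (mean 1.34, camera adjusted p = 1.44e-06, and adjusted p = 0.154 with an estimated correlation). Of these 5 rose over all genes and 9 adjusted over the list alone. The p53 targets were higher in 18 of 24 (mean 0.63, camera adjusted p = 0.000891, and adjusted p = 0.154 with an estimated correlation). Cdkn1a, Aen and Eda2r rose over all genes and 7 adjusted over the list alone, adding Phlda3, Sesn2, Plk2 and Bax. Endothelial adhesion and chemokine genes were higher in 14 of 16 (mean 0.63, camera adjusted p = 0.000826, and adjusted p = 0.403 with an estimated correlation). Over all genes 0 passed, and 7 rose adjusted over the list alone, among them the selectins Sele and Selp and the adhesion molecule Icam1. Smooth muscle markers were lower in 12 of 14 (mean -0.50, camera adjusted p = 1.06e-05, and adjusted p = 0.435 with an estimated correlation). Over all genes 4 fell, and 8 adjusted over the list alone. These 5 lists were those called by fry, with adjusted p of 0.0123, 0.00104, 0.00259, 0.0238 and 0.0300. In an exact permutation of transplant labels within diets (200 splits, two-sided, smallest possible p 0.005), added after seeing the data, the p53, MHC class II and adhesion lists each reached p = 0.005 (adjusted p = 0.0467; differences in mean log2 CPM 0.68, 1.07 and 0.59). In the same exact permutation interferon-stimulated genes reached 0.01 (adjusted p = 0.0700, 1.06) and smooth muscle markers 0.02 (adjusted p = 0.0933, -0.50). Without control CRD 2 the p53 mean was 0.95, and with the mitochondrial share as a covariate it was 0.44 (camera adjusted p = 0.126; range over 19 alternatives 0.000186 to 0.154).

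Endothelial markers were called as well in the averaged BMT comparison (15 of 18 higher, mean 0.49, camera adjusted p = 0.000821, and adjusted p = 0.475 with an estimated correlation). Mmrn2 and Egfl7 rose over all genes and 6 adjusted over the list alone. Cell cycle genes were higher in 26 of 26 (mean 1.16, camera adjusted p = 3.93e-06, and adjusted p = 0.533 with an estimated correlation). Kif20a, Ube2c and Mcm5 rose adjusted over the list alone. T and NK markers were higher in 13 of 16 (mean 1.22, camera adjusted p = 0.00936, and adjusted p = 0.627 with an estimated correlation), with 0 adjusted over the list alone. Matrix and fibrosis genes were lower (18 of 23, mean -0.25, camera adjusted p = 0.00485, and adjusted p = 0.475 with an estimated correlation). So were adipocyte markers (12 of 12, mean -0.81, 0.000821, and 0.533) and mast cell markers (10 of 11, mean -1.15, 0.00873, and 0.475). Adjusted over the list alone, Postn and Col15a1 fell in the matrix list, and Pck1, Cyp2e1, Adipoq and Retn in the adipocyte list. Cpa3 and Mcpt4 fell in the mast cell list, where Gata2 rose, and Mcpt4 also fell over all genes. The T and NK call ended without control chow 3 (0.0782), control CRD 1 (0.138) or BMT CRD 1 (0.0512), and the mast cell call without control CRD 1 (mean -0.36, 0.102). Without control CRD 2 the cell cycle mean was 1.82 and the T and NK mean 1.90, and without control CRD 1 the adipocyte mean was -0.44. With the thymocyte mean as a covariate the cell cycle mean was 0.24 and the T and NK mean 0.14, and with the mitochondrial share as a covariate the adipocyte mean was -0.13.

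Camera did not call the other 17 lists for the averaged BMT effect. Their mean log2 changes and adjusted p were 0.39 and 0.588 (senescence and secretory), -0.14 and 0.339 (cholesterol synthesis), and 0.13 and 0.588 (LXR targets). They were -0.26 and 0.381 (foam cell and lipid-associated macrophage), 0.21 and 0.911 (lipoprotein uptake and transcytosis), and -0.04 and 0.528 (proteoglycans), then 0.07 and 0.913 (immediate early and stress), -0.14 and 0.274 (circadian clock) and -0.06 and 0.588 (fibroblasts). For the remaining cell types they were 0.06 and 0.891 (macrophages), 0.21 and 0.154 (monocytes), and 0.81 and 0.404 (dendritic cells). They were -0.12 and 0.913 (neutrophils), 0.33 and 0.432 (B and plasma cells), 0.94 and 0.179 (erythroid cells), 0.64 and 0.890 (Schwann cells and neurons) and 0.46 and 0.588 (cardiac and skeletal muscle). Members went both ways in the foam cell list, where 5 rose and 6 fell adjusted over the list alone, and in the macrophage list, where again 5 rose and 6 fell. Among lipoprotein uptake genes, Plvap, a diaphragm protein of endothelial caveolae and fenestrae, rose and Vldlr, a lipoprotein receptor, fell. Median, mean and test differed in sign for 5 of these lists. Proteoglycans, fibroblasts and neutrophils had a median above 0 and a mean and test below it, and immediate early genes and macrophages a test below and a median and mean above. No called list had such a difference in any of the 7 comparisons.

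**Figure D2:**
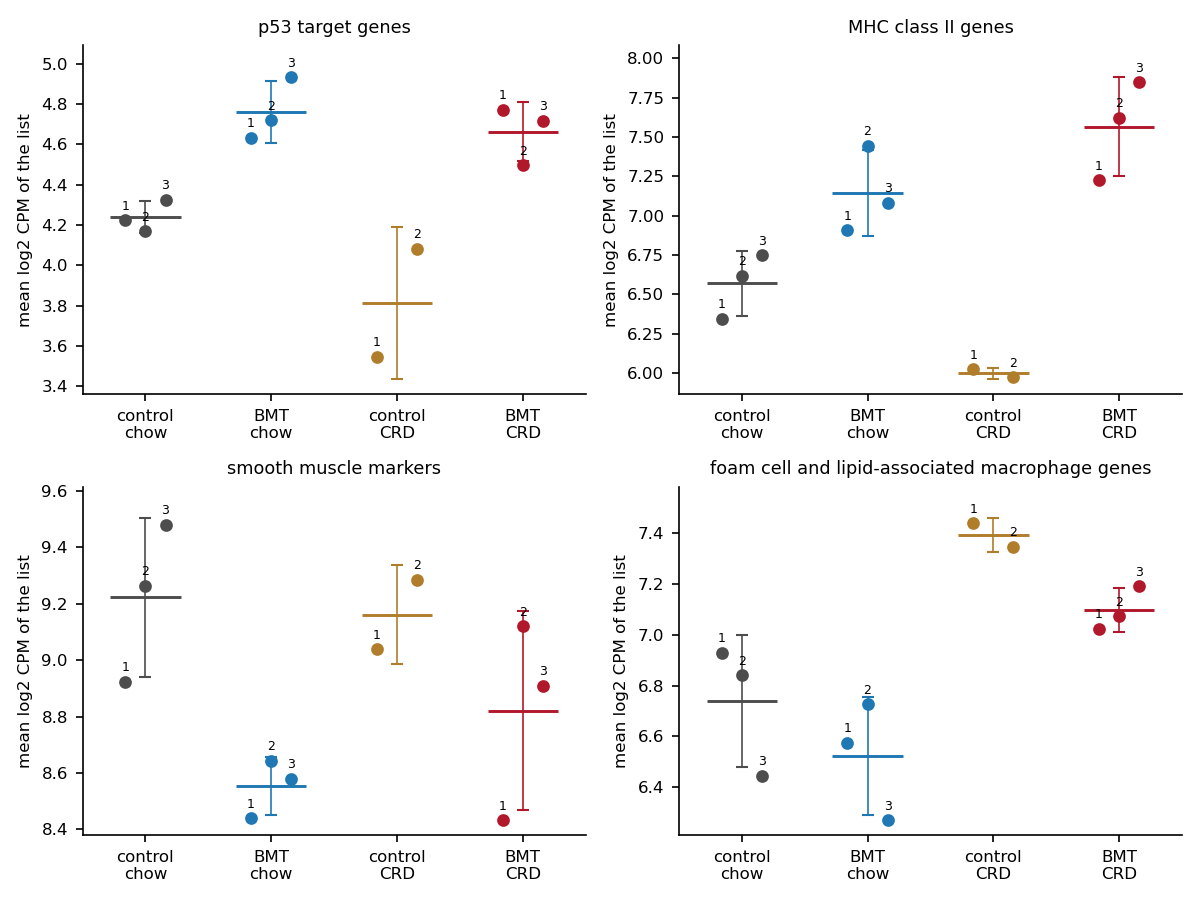
Mean log2 CPM of the p53 target, MHC class II, smooth muscle and foam cell lists by group (control chow, BMT chow, control CRD, BMT CRD); points are libraries numbered by replicate, horizontal lines are group means and error bars are SD. The MHC class II mean was 5.97 to 6.75 in the 5 control libraries and 6.91 to 7.85 in the 6 BMT libraries, and the foam cell mean was 6.27 to 6.93 in the 6 chow libraries and 7.02 to 7.44 in the 5 CRD libraries.

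The comparison of CRD with chow in control mice asked what 5 days of cholesterol feeding changed in the arterial wall. Foam cell and lipid-associated macrophage genes were higher in 20 of 22, by a mean of 0.54 (camera adjusted p = 7.98e-07, and adjusted p = 0.0857 with an estimated correlation), and the list was called by fry as well (adjusted p = 0.0323). None of the 22 passed over all genes, and 3 rose adjusted over the list alone (n = 3 and n = 2). They were Itgax, an integrin of dendritic cells and macrophages (16.2 ± 5.22 to 37.0 ± 4.99 CPM), and Mmp12, the macrophage elastase (151 ± 73.8 to 412 ± 71.9 CPM). The other was Lgals3, a galectin of macrophages (70.9 ± 20.2 to 205 ± 42.2 CPM). The mitochondrial share was 25.5% and 17.2% in the control CRD libraries against 7.04% to 10.5% in control chow, and 19654 and 18864 genes were detected against 21240 to 22371. With that share as a covariate the foam cell mean was 0.32 and the list was not called (camera adjusted p = 0.0953). The edgeR test called 1 gene, Gm42688, which had 3.32 ± 0.482 CPM on chow and 0 counts in both CRD libraries, at least 45.9-fold lower (adjusted p = 0.0207). In this test 1624 genes had an unadjusted p under 0.05. That call ended without control chow 1, 2 or 3 or control CRD 2 (0.0542 to 0.0931). The number of called genes was 0 without each control chow library, 1 (another gene) without control CRD 2 and 13 without control CRD 1.

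T and NK markers were also called in control mice on CRD (13 of 16 higher, mean 0.84, camera adjusted p = 0.00303, and adjusted p = 0.689 with an estimated correlation), with Nkg7 and Il7r risen adjusted over the list alone. Fibroblast markers were lower in 14 of 14 (mean -0.70, 0.0121, and 0.689). Erythroid markers (mean 1.08, 0.0236, and 0.689), neutrophil markers (1.31, 0.0399, and 0.689) and cell cycle genes (0.41, 0.0399, and 0.854) were higher, and mast cell markers were lower (-0.79, 0.0439, and 0.689). In these and the fibroblast list 0 members passed adjusted over the list alone. The thymocyte mean was 0.29 and 3.70 in control CRD 1 and 2. Without control CRD 2 the cell cycle mean was -0.90 and the T and NK mean -0.50 (camera adjusted p = 0.381), and the fibroblast mean was -0.46 (0.570) and the erythroid mean -0.97 (0.697). Without control chow 3 the T and NK call ended as well (0.202) with that of the cell cycle (0.569). The erythroid call also ended without control chow 2 or 3, and the fibroblast call without control chow 2. Without control CRD 1 the neutrophil mean was 0.08 and the mast cell mean -2.37, and the neutrophil mean was 2.65 without control chow 1. The mast cell call ended without control chow 1, 2 or 3, and the neutrophil call without control chow 2 or 3. Over the left-out libraries the mast cell mean ran from -2.37 to -0.75. In all 7 lists were called, 3 without control chow 2, 2 without control chow 3 and 3 without control CRD 2, and the foam cell call was kept without each of the 5 libraries but not with the mitochondrial share as a covariate.

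The comparison of CRD with chow in BMT mice asked the same of the arterial wall after marrow transplantation. Foam cell genes were higher in 19 of 22, by a mean of 0.57 (camera adjusted p = 8.13e-08, and adjusted p = 0.0662 with an estimated correlation), and by fry adjusted p = 0.0440. Of its members 3 rose adjusted over the list alone (n = 3 and n = 3). They were Msr1, a scavenger receptor for modified lipoproteins (10.9 ± 2.86 to 33.2 ± 6.94 CPM), Plin2, a lipid droplet coat protein (173 ± 23.3 to 293 ± 26.9 CPM), and Ctsb, a lysosomal protease (1460 ± 197 to 3219 ± 509 CPM). Over all genes 0 were called by the edgeR quasi-likelihood test (smallest adjusted p = 1) and 0 by limma voom, against 37 by the DESeq2 Wald test. By edgeR 934 genes had an unadjusted p under 0.05. Interferon-stimulated genes were higher in 25 of 27 (mean 0.59, camera adjusted p = 1.78e-08, and adjusted p = 0.485 with an estimated correlation) and cholesterol synthesis genes lower in 20 of 23 (mean -0.44, 0.0106, and 0.485). Cell cycle genes were lower in 25 of 26 (mean -1.05, 2.13e-07, and 0.485) and T and NK markers in 14 of 16 (mean -1.20, 0.00285, and 0.485). Thymocyte means were 4.02, 5.75 and 6.36 in BMT chow and 4.47, 3.74 and 1.77 in BMT CRD 1 to 3. The other called lists were MHC class II (0.36, 0.0126, and 0.485), matrix (0.31, 0.00270, and 0.485), smooth muscle (0.29, 0.00518, and 0.485), fibroblast (-0.32, 0.0244, and 0.569) and cardiac and skeletal muscle (1.06, 0.000119, and 0.485). Outside the foam cell list 0 members of any called list passed adjusted over the list alone.

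Single libraries moved several of these calls in BMT mice. The 10 called lists became 6 without BMT chow 3 and 5 without BMT CRD 3. Without BMT chow 3 the cell cycle mean was -0.57, the T and NK mean -0.64 (0.121), the cholesterol synthesis mean -0.27 (0.193) and the matrix mean 0.20 (0.233), and the MHC class II call ended (0.237). Without BMT CRD 3 the calls of cholesterol synthesis (0.0604), T and NK markers (0.0604), smooth muscle markers (0.0604), MHC class II (0.159) and fibroblast markers (0.292) ended. Smooth muscle markers had a mean of 0.14 (0.244) without BMT CRD 2 and 0.45 without BMT CRD 1. The fibroblast call ended without BMT chow 2 (0.244), BMT chow 3 (0.104) or BMT CRD 2 (0.175), and the mean was -0.59 without BMT CRD 1. The matrix mean was 0.20 without BMT CRD 1, and the cardiac mean was 0.68 (0.0635) without BMT chow 1 and 0.57 without BMT CRD 1. With the thymocyte mean as a covariate the cell cycle mean was -0.24 and the T and NK mean -0.11, and the camera direction of the T and NK markers turned to higher. Without both BMT chow 2 and 3 the cell cycle mean was -0.06 (0.491), the cholesterol synthesis mean -0.05 (0.672), the T and NK mean 0.42 and the fibroblast mean 0.05 (both 0.881).

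The CRD effect averaged over transplant status, also added after seeing the data, used all 6 chow and 5 CRD libraries. Foam cell and lipid-associated macrophage genes were higher in 19 of 22, by a mean of 0.56 (camera adjusted p = 2.79e-12, and adjusted p = 0.0162 with an estimated correlation). This was the 1 list of the 28 that held with an estimated correlation, in any of the 7 comparisons, and fry called it too (adjusted p = 0.00404). Over all genes 0 of its members passed, and 9 rose adjusted over the list alone, namely Itgax, Msr1, Lpl, Cd36, Plin2, Mmp12, Trem2, Ctsb and Lgals3. Lgals3 had a log2 change of 1.23 (SE 0.219, adjusted p = 0.217), Ctsb 0.98 (SE 0.178, 0.217), Trem2, a lipid receptor of macrophages, 1.06 (SE 0.342, 0.588) and Msr1 1.10 (SE 0.225, 0.273) over all genes by edgeR. In an exact permutation of diet labels within transplant status (200 splits, two-sided, smallest possible p 0.005) the difference in mean log2 CPM was 0.61 (p = 0.005, adjusted p = 0.0700), and all 5 CRD libraries were above all 6 chow libraries. In the same permutation the difference for cholesterol synthesis genes was -0.44 (p = 0.005, adjusted p = 0.0700). The foam cell call was kept in all 19 alternatives, with means from 0.41 to 0.65.

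Interferon-stimulated genes were also called for the averaged CRD effect (23 of 27 higher, mean 0.25, camera adjusted p = 0.000118, and adjusted p = 0.549 with an estimated correlation). So were fibroblast markers (14 of 14 lower, mean -0.51, 0.000652, and 0.549) and neutrophil markers (7 of 9 higher, mean 1.16, 0.00591, and 0.473). The cholesterol synthesis genes were lower in 19 of 23 (mean -0.38, camera adjusted p = 0.0301, and adjusted p = 0.473 with an estimated correlation). LXR targets, some of which move cholesterol out of cells, were higher in 9 of 12 (mean 0.27, camera adjusted p = 0.0406, and adjusted p = 0.473 with an estimated correlation). Members risen adjusted over the list alone were the cholesterol exporters Abca1 (1.60-fold) and Abcg1 (2.30-fold). Erythroid markers were higher in 8 of 9 (mean 0.31, 0.0406, and 0.766). In the interferon, fibroblast, neutrophil, cholesterol synthesis and erythroid lists 0 members passed adjusted over the list alone. The edgeR test called 1 gene, Gm42688 (adjusted p = 0.0447, lower), and 1569 genes had an unadjusted p under 0.05. The count was 14 without control CRD 1, 3 without BMT chow 1, 1 without control CRD 2 and 0 without any other library.

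The 7 lists called for the averaged CRD effect became 4 without BMT chow 1, control CRD 2 or BMT CRD 3. The LXR call ended without control chow 1, BMT chow 1, 2 or 3, control CRD 2 or BMT CRD 1 or 3 (0.0516 to 0.210; mean 0.16 without control CRD 2). The cholesterol synthesis call ended without control chow 1, BMT chow 3, control CRD 2 or BMT CRD 3 (0.0598 to 0.144), and its mean was -0.77 without control CRD 1. The fibroblast call ended without control CRD 2 (0.0822), and the neutrophil call without BMT chow 1 (0.0543) or control CRD 1 (mean 0.26, 0.113). Its mean was 1.83 without control chow 1 and 0.77 without control CRD 2. The erythroid mean lay between -0.44 (without control CRD 2) and 0.60 (without control chow 1), and its call ended without control chow 2 or 3, BMT chow 1, control CRD 2 or BMT CRD 2 or 3. The interferon mean was 0.45 without control chow 1, 0.15 without control chow 3 and 0.17 without control CRD 1. Cd68, a lysosomal protein of macrophages chosen after its values were seen, had 174 ± 46.4 and 399 ± 57.0 CPM in control mice on chow and CRD and 213 ± 38.8 and 457 ± 47.8 CPM in BMT mice. Its averaged log2 change of 1.15 (SE 0.162, edgeR adjusted p = 0.0743) did not pass. Its macrophage list was not called (mean 0.10, median -0.03, camera adjusted p = 0.0760), with Ms4a7, Cd68 and Fcgr1 risen adjusted over the list alone.

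The interaction asked whether the diet acted differently in the arteries of BMT and control mice. By the edgeR quasi-likelihood test 0 genes were called (smallest adjusted p = 0.0659, for Gm42688), with 1417 at an unadjusted p under 0.05, 0 called by limma voom and 121 by the DESeq2 Wald test. Without control CRD 1 the edgeR count was 16 and without control CRD 2 it was 1. Camera called 5 lists. T and NK markers had a lower CRD effect in BMT mice in 16 of 16 (mean difference -2.03, camera adjusted p = 6.92e-06, and adjusted p = 0.743 with an estimated correlation). Nkg7, a granule protein of cytotoxic cells, was the 1 member past the threshold adjusted over the list alone. Cell cycle genes were lower in 26 of 26 (mean -1.46, 9.57e-07, and 0.743). Cardiac and skeletal muscle markers were higher in 13 of 14 (mean 1.93, 0.000175, and 0.743), as were matrix genes in 21 of 23 (mean 0.47, 0.0457, and 0.748). Interferon-stimulated genes were higher in 23 of 27 (mean 0.68, 0.0106, and 0.748), where Oasl2 rose adjusted over the list alone. Fry called 0 of the lists (smallest adjusted p over these 5 lists 0.411). The foam cell list had a mean difference of 0.03 (camera adjusted p = 0.729), so its CRD effect was not shown to differ with transplant status.

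Left-out libraries decided most of the interaction calls. Without control CRD 2 the cell cycle mean was -0.16 (camera adjusted p = 0.104) and the T and NK mean -0.69, and 3 lists were called, as without BMT CRD 1. Without control CRD 1 the cardiac call ended (1.64, 0.104). The interferon call ended without control chow 1 (0.29, 0.185), control CRD 1 (0.137) or BMT CRD 1 (0.120). The matrix call ended without control chow 1 or 3, BMT chow 3, control CRD 1 or 2, or BMT CRD 1 or 2 (0.0772 to 0.499). Without both BMT chow 2 and 3, where thymocyte genes were highest, 1 list was called. Across all genes the CRD effects in control and BMT mice had Pearson's r = 0.0393 and Spearman's rho = 0.00455, with 49.4% of the 20507 genes of the same sign. Across the 9910 genes with a mean log2 CPM of at least 3 r was 0.0307; genes are not independent replicates. Over all genes r lay between -0.0643 (without BMT chow 3) and 0.105 (without BMT CRD 1), with 0.0155 without control chow 2, 0.0167 without BMT chow 2, 0.0851 without control CRD 2, 0.0591 without BMT CRD 2 and 0.0919 without BMT CRD 3.

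**Figure D3:**
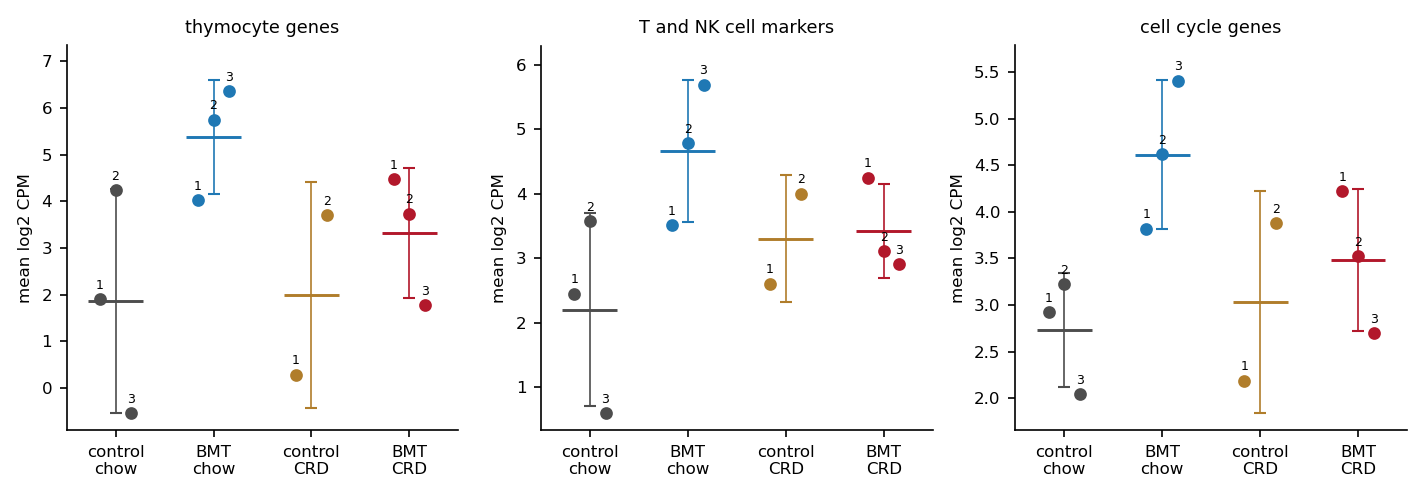
Mean log2 CPM of 13 thymocyte genes, of the T and NK cell markers and of the cell cycle genes by group (control chow, BMT chow, control CRD, BMT CRD); points are libraries numbered by replicate, horizontal lines are group means and error bars are SD. The thymocyte mean was highest in BMT chow 2 (5.75) and BMT chow 3 (6.36), and the other 9 libraries lay between -0.54 and 4.47.

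Ldlr transcripts were counted in every library, and counts outside the disrupted part of the gene say nothing about the receptor. Ldlr was at 4.99, 19.1 and 19.6 CPM in control chow 1 to 3, and 10.6, 31.4 and 30.8 CPM in BMT chow 1 to 3. It was at 2.32 and 1.20 CPM in control CRD 1 and 2, and 14.7, 26.6 and 12.4 CPM in BMT CRD 1 to 3. The averaged BMT difference was 2.04 on the log2 scale (SE 0.456, edgeR adjusted p = 0.0587), which did not pass. Cells from the wild-type marrow can carry an intact Ldlr gene.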

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

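The tests of a library batch, of the smooth muscle share and of the mitochondrial share were chosen after the result was seen, as were the averaged comparisons. The tests of genomic DNA, of a single repeat and of thymus tissue were written down before they were run. The patterns they address had been seen by then, and the thymus test concerned libraries picked for their high T cell genes.

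In 5 lists the CRD effect differed between BMT and control mice by camera on the interaction. The mean log2 difference was -2.03 for T and NK cell markers, -1.46 for cell cycle genes, 1.93 for cardiac and skeletal muscle markers, 0.68 for interferon-stimulated genes and 0.47 for matrix and fibrosis genes. With an estimated correlation none of the 5 was called (smallest adjusted p = 0.743).

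T cell and cell cycle genes stood high in BMT chow 2 and 3, where Lck reached 933 CPM and Cd8b1 453 CPM, both in BMT chow 3. Thymus tissue taken along with the aortic arch is a candidate source: 13 genes of developing thymocytes, written down before the test, had a mean log2 CPM of 6.05 in these libraries against a median of 3.70 in the other 9, a difference of 2.35, and 3 of the 13 (Cd4, Cd8b1 and Lck) are also in the T and NK list. Of the most abundant of these genes besides Lck and Cd8b1, Tcf7 was at 135 and 309 CPM and Dntt at 120 and 209 CPM in BMT chow 2 and 3. Rag1 was at 96.5 and 143 CPM there and at most 35.1 CPM (BMT CRD 1) elsewhere. Rag2 was at 15.5 and 48.3 CPM in BMT chow 2 and 3, but also at 27.0 CPM in control CRD 2. The labels name no sort that would remove such cells, and the genes were also present in other libraries, with means of 4.24 in control chow 2 and 4.47 in BMT CRD 1. A change of T cells or of cycling cells in the arterial wall itself after transplantation stays open and was not tested.

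The repeat-overlapping gene models were higher in every BMT library than in every control library, the lowest BMT sum being 32.1 times the highest control sum. Their log2 CPM moved together over the 6 BMT libraries, with a median pairwise Pearson r of 0.957, in line with 1 repeat counted in several models rather than several genes. Genomic DNA carried into the BMT libraries stays open: olfactory and vomeronasal receptor genes, 1782 in all, summed to 24.5 ± 10.6 CPM in control and 20.3 ± 3.10 CPM in BMT libraries (ratio 0.830, exact permutation p = 0.445, two-sided), but the least receptor signal that such DNA would add, 0.921 CPM, is smaller than that spread, so the bound set beforehand was too wide to decide. A batch of library preparation that followed transplant status cannot be told apart from the transplant, since the labels give no batch, and it could reach every BMT result. Transcription of the repeat in the tissue of mice given irradiation or marrow stays open as well and was not tested.

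Smooth muscle genes were lower and MHC class II genes higher in BMT libraries. A smaller share of smooth muscle alone would raise the markers of other cell types alike. Endothelial and adipocyte markers moved apart by 1.37 on the log2 scale (exact permutation p = 0.035, two-sided, smallest possible 0.005). That pair was picked after the list results were seen, so the permutation cannot decide the question. Singly, the exact permutation gave adjusted p = 0.14 for the endothelial and 0.187 for the adipocyte markers. With the mitochondrial share as a covariate the endothelial and adipocyte means were 0.18 and -0.13 in the averaged comparison. A smaller share of smooth muscle stays open, alone or together with the mitochondrial share. The mitochondrial share alone is argued against as the whole cause, since with it as a covariate both lists were still called in the averaged comparison (larger camera adjusted p = 0.00734), with means of 1.45 (MHC class II) and -0.43 (smooth muscle) against 1.34 and -0.50 without it. That argument rests on the preset correlation, since with an estimated correlation neither list was called even without the covariate (adjusted p = 0.154 and 0.435). With the covariate the number of called genes became 8. Of the 43 named genes 2 then kept their call and 43 their sign. A batch along the groups stays open here too. Changes of the wall and of its immune cells after irradiation and marrow replacement stay open as well and were not tested.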

How the results depend on the processing

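The tests with covariates for sex-linked genes, thymocyte genes and the mitochondrial share, the fit without BMT chow 2 and 3, and everything on the averaged comparisons were chosen after the results were seen. Where a value changed, the cause was not tested unless a sentence names it. Counts of called genes are given in the order BMT on chow, BMT on CRD, CRD in control, CRD in BMT, interaction, averaged BMT and averaged CRD; they were 9, 9, 1, 0, 0, 243 and 1 with the edgeR test. The DESeq2 Wald test gave 614, 887, 314, 37, 121, 1767 and 214. Limma voom gave 171 for BMT on chow, 4 for BMT on CRD, 0 for CRD in control and 3 for averaged CRD. With only the groups compared there were 4 for BMT on CRD and 0 for CRD in control. With the replicate number as a block there were 0 for CRD in control, 76 for averaged BMT and 0 for averaged CRD. The pairing check gave same-number correlations between -0.0641 and 0.104 against -0.104 to 0.0677 for different numbers. Control CRD 1 and 2 mirror each other once centred on their group, and these extremes come from them. The ranges therefore cannot decide whether the numbers pair the libraries. For CRD in control, averaged BMT and averaged CRD the sex-linked term gave 0, 41 and 0, the thymocyte covariate 0, 15 and 0, and the mitochondrial share 0, 8 and 0, with 5 for BMT on CRD. Without BMT chow 2 and 3 there were 4 for BMT on chow, 9 for averaged BMT and 0 for averaged CRD. Upper-quartile factors and no filter each gave 0 for averaged CRD. Leaving out each library in turn gave 4 to 16, 6 to 25, 0 to 13, 0 to 0, 0 to 16, 21 to 378 and 0 to 14. Without a control CRD library its group holds 1, and the lone library is assumed to vary like the other groups.

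Called lists, in the same order 13, 8, 7, 10, 5, 11 and 7, were 0, 0, 0, 0, 0, 0 and 1 with an estimated correlation and 1, 3, 1, 1, 0, 5 and 1 by fry. The thymocyte covariate gave 8 for BMT on chow and 5 for CRD in BMT, and the sex-linked term 3 for CRD in control. The mitochondrial share gave 2 for BMT on CRD, 4 for CRD in control, 2 for the interaction and 5 for averaged BMT. Without BMT chow 2 and 3 there were 5 for CRD in BMT and 1 for the interaction. Leaving out each library gave 10 to 14, 2 to 8, 2 to 7, 5 to 13, 3 to 7, 9 to 12 and 4 to 8. The correlation of BMT effects across genes was 0.407 at a mean log2 CPM of at least 3, and ran from 0.0198 to 0.140 with each library left out; that of CRD effects ran from -0.0643 to 0.105. List directions turned with the mitochondrial share for BMT on CRD, in endothelial (-0.14), adipocyte (0.47) and cardiac and skeletal muscle markers (-0.00341). They turned for cell cycle genes on CRD in control without control CRD 2 (-0.90, against 0.94 without control CRD 1), and with the thymocyte covariate for T and NK markers on CRD in BMT (-0.11) and in averaged BMT (0.14), where the mean kept its sign and the camera direction did not. The mean changed sign and the camera direction did not in 8 more cases. Without control CRD 2 these were T and NK (-0.50) and erythroid markers (-0.97) on CRD in control and erythroid markers in averaged CRD (-0.44), the last also without BMT CRD 3 (-0.30). Without BMT chow 2 and 3 they were MHC class II (-0.13) and erythroid markers (-0.64) for BMT on chow, and fibroblast (0.05) and T and NK markers (0.42) for CRD in BMT.

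Of 62 results for named genes, the DESeq2 size factors, the DESeq2 Wald test and the filter of at least 10 counts in at least 6 libraries left 62 past the threshold in the same direction, upper-quartile factors 61, no filter 56, voom 49, the block 26, the sex-linked term 24, the thymocyte covariate 19 and the mitochondrial share 15, and none of the 62 turned. Without BMT chow 2 and 3, 5 of 52 held, and with only the groups compared 9 of 19. Leaving out each library kept 234 results and ended 343, all in the same direction. Of 61 list results, upper-quartile factors kept 60, the block 59, the sex-linked term 53, the thymocyte covariate 45, the mitochondrial share 36, fry 12 and an estimated correlation 1. Each result was run under the alternatives fixed in advance for it. For the lists these were upper-quartile factors, the block, an estimated correlation, fry and left-out libraries, and for the correlations across genes the level of expression and left-out libraries. The interaction and the averaged comparisons have no version with only the groups compared, since they use all 4 groups. Depth sets the least level seen, 0.0727 to 0.145 CPM per library at 3 counts.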

Other observations

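The tests over other splits of the libraries were all chosen after the results they concern were seen, and the genes named here outside the lists were chosen after their values were seen.

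Macrophage genes moved both ways in BMT mice, averaged over diets. Adjusted over the list alone, 6 markers fell: Cd163 (log2 change -1.26, SE 0.279), Timd4 (-1.26, SE 0.351), Pf4 (-0.59), Mertk (-0.58), Mrc1 (-0.49) and Cbr2 (-0.43). In the same list 5 rose, the complement genes C1qa (2.07, SE 0.416) and C1qb (1.15, SE 0.263), Cx3cr1 (0.86), Fcgr1 (0.60) and Adgre1 (0.41). Ccr2, the chemokine receptor of recruited monocytes, was 2.27-fold higher and Irf8 1.89-fold higher, each risen adjusted over its own list alone. Over all genes C1qa passed in the edgeR test (adjusted p = 0.0441), and its call ended without each library but BMT chow 1 (up to 0.125); the others had adjusted p of at least 0.0570. The macrophage list as a whole was not called (camera adjusted p = 0.891).

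After the single called gene, the genes nearest the threshold on CRD were Mpeg1, Slc40a1 and Hpgds, which belong to none of the lists tested. For the averaged CRD effect the macrophage list was not called, while the foam cell and lipid-associated macrophage list was. Mpeg1, a pore-forming protein, had a log2 change of 1.36 (SE 0.182), Slc40a1, the iron exporter ferroportin, 1.27 (SE 0.169), and Hpgds, a prostaglandin synthase, 1.33 (SE 0.179), averaged over transplant status, each with an edgeR adjusted p = 0.0591, which did not pass. Mpeg1 was at 66.2 ± 16.9 and 259 ± 13.1 CPM in control mice on chow and CRD (n = 3 and n = 2) and at 124 ± 35.1 and 210.2 ± 20.8 CPM in BMT mice (n = 3 and n = 3).

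Sex-linked transcripts differed between libraries of a group. Xist was at 129 CPM in control chow 2, 262 CPM in BMT chow 2 and 251 CPM in BMT CRD 1, with Ddx3y at or below 0.386 CPM in these. The other 8 libraries had Ddx3y at 77.2 to 159 CPM, and among them Xist was at 8.79 and 9.81 CPM in control CRD 1 and 2 and at most 1.89 CPM in the rest. Haemoglobin genes took 1.70% to 10.7% of counts.

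For the averaged BMT comparison 243 genes were called. At most 3 were called in 99 others of the 200 possible splits of the libraries within diets. These were drawn at random with a fixed seed to keep to 100 fits. Only the real split, 1 in 100, reached its count. That share covers this fit alone, and the comparison was added after seeing the data. The count was 21 without BMT chow 2 and 8 with the mitochondrial share as a covariate. The 11 lists called there were reached or passed by 7 splits in 100, the highest other split calling 14, so chance is not excluded for the number of lists. For the averaged CRD comparison the single called gene was reached by 9 of 100 splits (highest other 2) and the 7 lists by 20 of 100 (highest other 12), so chance is not excluded for either. BMT against control on chow and CRD against chow in BMT mice allow only 10 splits, too few for a share under 0.05. On chow the real split called 9 genes (highest other 1) and 13 lists (highest other 10), and in BMT mice 0 genes (highest other 0) and 10 lists (highest other 8), with as large a result in 1, 1, 10 and 1 of the 10 splits. The median number of lists in the other splits was 4 for averaged BMT, 4 for averaged CRD, 5 on chow and 5 in BMT mice.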
